A study of Homo sapiens with 24 samples.

How the data were processed

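RNA was measured by sequencing in 24 libraries of A549 and H1299 cells carrying an empty vector or FLAG-tagged SIRT6 in its wild-type, K3R or K3Q form. Per the labels, cells were grown in RPMI1640 medium with serum, RNA was extracted with RNAiso Plus, and libraries were made with a SMARTer kit. The deposited table holds counts, unnormalised, of reads for 59385 gene symbols in each library. The submitters' processing notes name FastQC, cutadapt, STAR, featureCounts and the genome build GRCh38. Tool versions, the strand setting of the counting and the annotation release are not given in the sources used here. Reads of near-identical gene copies, and reads of the introduced and the cells' own SIRT6, cannot be separated in these counts. Coordinates come from GENCODE 29 on GRCh38, joined by symbol, which matched 40216 of the 59385 symbols and 16167 of 18036 tested genes. That release may differ from the one the submitters used.

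Each line was fitted on its own 12 libraries, 3 per construct. Genes were filtered with filterByExpr, libraries were scaled by TMM, and the edgeR quasi-likelihood test (edgeR 4.0.16, R 4.3.3) was run with construct and batch as terms. Adjusted p-values are Benjamini-Hochberg over the genes tested in that line (16120 in A549, 16262 in H1299), and a gene passed under 0.05. Interaction tests between the lines used all 24 libraries and 18102 genes. CPM values are means ± SD over 3 libraries, and principal components were taken on log2 CPM with a prior count of 2. Log2 changes carry the standard error implied by the quasi-likelihood F statistic, the absolute change over the square root of F. Gene lists, 39 in number with 38 measured in each line, were tested by camera in limma 3.58.1 with a preset correlation of 0.01 and again with an estimated one. List p-values are adjusted over the lists of a comparison. With the preset correlation 10, 14, 14, 1, 10 and 10 of 38 lists passed in A549 for WT, K3R and K3Q against Ctr, K3R and K3Q against WT, and K3Q against K3R, and 5, 2, 10, 7, 10 and 4 in H1299, and not all of these are described. With an estimated correlation 0 passed in each of these 12 comparisons. Correlations of log2 changes across genes that share Ctr libraries were set against 20 simulations without effects.

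The groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. SIRT6 and the other sirtuins are named in each comparison. For WT against Ctr and K3Q against K3R, the rule names the 8 largest rises and the 8 largest falls among genes that passed, had a mean log2 CPM of at least 1 and moved the same way in all 3 differences matched by replicate and batch. It names 5 and 5 for K3R and K3Q against Ctr, 3 and 3 for K3R and K3Q against WT, and the 3 lowest adjusted p in each direction for the interactions. For a list that passed with the preset correlation, it names the 3 members with the largest change among those that passed, or the 2 with the lowest p where none did. Where no gene passed, the 3 with the lowest p are named as not passing. Clone names, pseudogenes, antisense names and sex-linked marker genes are counted and not named. A few other genes that the rule names, and 1 list result that rests on such a gene, are not reported here.

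The alternatives were no batch term, the replicate number as a block, RLE scaling, no low-count filter, DESeq2 1.42.0, all 24 libraries in one fit, the libraries of biological replicate 1 summed, batch 2 alone, an estimated correlation for lists and leaving out each library. The fits of batch 2 alone and of summed replicate 1 held no batch or replicate term. Summing the near-identical A549 K3Q pair, with and without the block, leaving out biological replicate 2 and leaving out libraries for the correlations were chosen after seeing the data. Libraries of the same replicate number moved together in H1299 and, for Ctr, WT and K3R, in A549. Correlations between constructs of the deviations from the group mean at the same number were 0.134 to 0.549 and 0.379 to 0.749. Batch was not removed, so these correlations also hold the batch shift and do not by themselves show pairing by number. Within batch 2, libraries 2-2 and 1-2 differed over the constructs together, as given under the other observations. For A549 K3Q at 2-2 the correlations were 0.0569 to 0.119, so the number does not pair that library. It enters the block terms and the spread of every block fit of A549 and of both lines together. All of those block counts carry that doubt, those that compare A549 K3Q most directly.

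The procedure was tested on simulated data with 100 genes changed at each fold. At 1.5-fold it recovered 22% in A549 and 25% in H1299, and at 3-fold 85% and 87%, with 8 and 5 false calls among 15844 and 16000 genes. Changes under 1.5-fold are therefore mostly below what the fit of construct and batch can show with 3 libraries per group. The fit with the replicate number as a block was not tested in this way.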

Results

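RNA-seq was used to ask how forced expression of SIRT6, an NAD-dependent deacylase that acts on chromatin, alters transcription in lung cancer cells, and whether mutants that block or imitate acetylation of SIRT6 act differently from the wild-type protein. The cells were A549 and H1299, established human lines of non-small cell lung cancer. Each line carried a lentivirus for FLAG-tagged SIRT6 or the empty vector (Ctr). The SIRT6 was wild type (WT), an acetylation-deficient mutant (K3R) or an acetylation-mimetic mutant (K3Q). K3R and K3Q are the names of the constructs, and the labels do not give the positions of the changed lysines. The 2 lines and 4 constructs gave 8 groups of 3 libraries, 24 in all. Within each group the libraries were biological replicate 1 in batch 1 (library 1-1), biological replicate 1 in batch 2 (library 1-2) and biological replicate 2 in batch 2 (library 2-2). The labels do not say whether libraries 1-1 and 1-2 came from one culture, so part of the spread behind every p-value may be technical. Total gene counts per library ran from 16434492 to 19412274 in A549 and from 14943189 to 22856407 in H1299.

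The libraries of A549 parted first by replicate and not by construct. On the first principal component of log2 CPM (37.7% of the variance), the 2-2 libraries of Ctr, WT and K3R scored between 50.95 and 53.74, and their 1-1 and 1-2 libraries between -31.57 and 1.47. The 3 K3Q libraries of A549, 2-2 included, scored between -36.16 and -12.08. In H1299 the first component (29.94% of the variance) separated WT and K3R, which scored between 7.31 and 52.99, from Ctr and K3Q, which scored between -38.36 and -11.61. WT 2-2 and K3R 2-2 of H1299 stood apart from the other libraries of their groups, at 52.99 and 45.29 against 15.24 and 10.71 or less. A549 K3Q libraries 1-2 and 2-2 were nearly identical: their chi-square per degree of freedom over genes was 2.60, against 16.1 to 71.5 in the 23 other pairs of libraries of one group. That value is above sampling noise, but separate preparations of one RNA could give it, so the pair may not be independent replicates. Both libraries were kept, and A549 K3Q results at n = 3 carry that doubt. The number of genes called by edgeR in each A549 K3Q comparison is also given with the pair summed to 1 library. The DESeq2 counts and the counts within lists were not redone with the pair summed. Mitochondrially encoded transcripts took 6.04% to 8.32% of the counts in A549 and 2.22% to 3.73% in H1299.

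**Figure D1:**
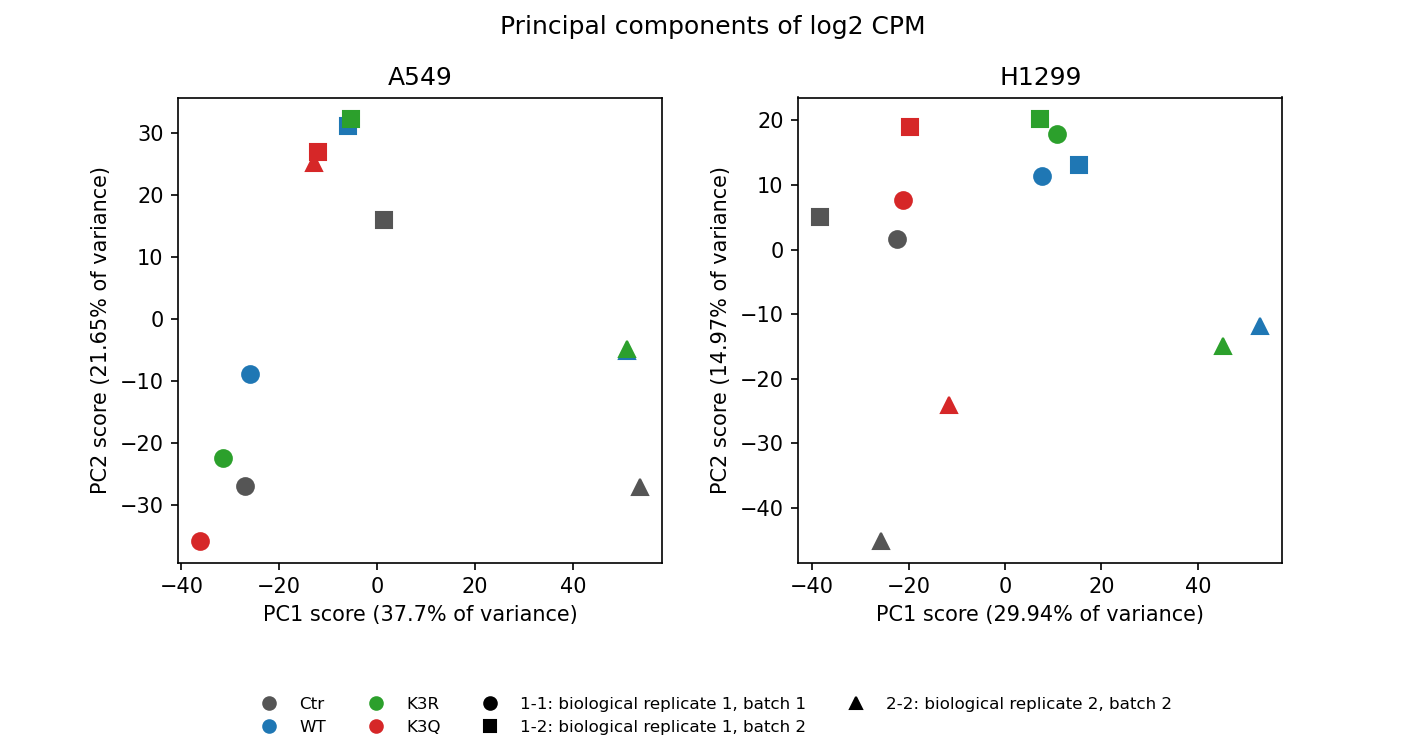
Scores of the 12 libraries of each line on the first 2 principal components of log2 CPM, each axis with its share of the variance. Colours are constructs and symbols are the replicate and batch. In A549 the 2-2 libraries of Ctr, WT and K3R lie to the right, at 50.95 or more, and K3Q 2-2 lies beside K3Q 1-2.

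SIRT6 transcript rose with every construct in both lines. In A549, SIRT6 stood at 26.0 ± 4.77 CPM in Ctr (mean ± SD, n = 3), 2242 ± 776 in WT, 2291 ± 936 in K3R and 1584 ± 112 in K3Q. In H1299 it stood at 39.4 ± 5.43 CPM in Ctr, 3984 ± 2399 in WT, 4332 ± 1651 in K3R and 13620 ± 2176 in K3Q. The log2 fold changes against Ctr were 6.37 ± 0.28 (SE), 6.39 ± 0.28 and 5.93 ± 0.27 for WT, K3R and K3Q in A549, and 6.65 ± 0.44, 6.78 ± 0.44 and 8.43 ± 0.48 in H1299, with adjusted p between 1.73e-06 and 1.4e-05 (edgeR quasi-likelihood test, Benjamini-Hochberg). Reads of the introduced copy and of the cells' own gene (GRCh38 chromosome 19, 4174109 to 4182604, minus strand) are counted together, and the mutants are not told apart from the wild type by these counts. In H1299, SIRT6 was 3.43-fold higher in K3Q than in WT (log2 1.78 ± 0.35, adjusted p = 0.0183) and higher in 3 of 3 matched libraries. That call was lost without WT 1-1 (log2 1.51, adjusted p = 0.0894), without WT 1-2 (1.53, adjusted p = 0.0547), without K3Q 1-1 (1.65, adjusted p = 0.104) and in batch 2 alone (1.47, adjusted p = 0.312). K3Q against K3R in H1299 gave a log2 difference of 1.66 ± 0.35 that did not pass (adjusted p = 0.0592), and with the replicate number as a block it passed (1.73, adjusted p = 0.000873). It did not pass with biological replicate 1 summed (1.56, adjusted p = 0.4) or in batch 2 alone (1.54, adjusted p = 0.595). SIRT6 did not differ detectably between constructs in A549, where the log2 differences were 0.03 for K3R against WT, -0.44 for K3Q against WT and -0.47 for K3Q against K3R. None of SIRT1, SIRT2, SIRT3, SIRT4, SIRT5 and SIRT7 passed in any of the 12 comparisons within a line (lowest adjusted p = 0.21, SIRT5 in H1299 K3Q against WT, log2 0.29).

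**Figure D2:**
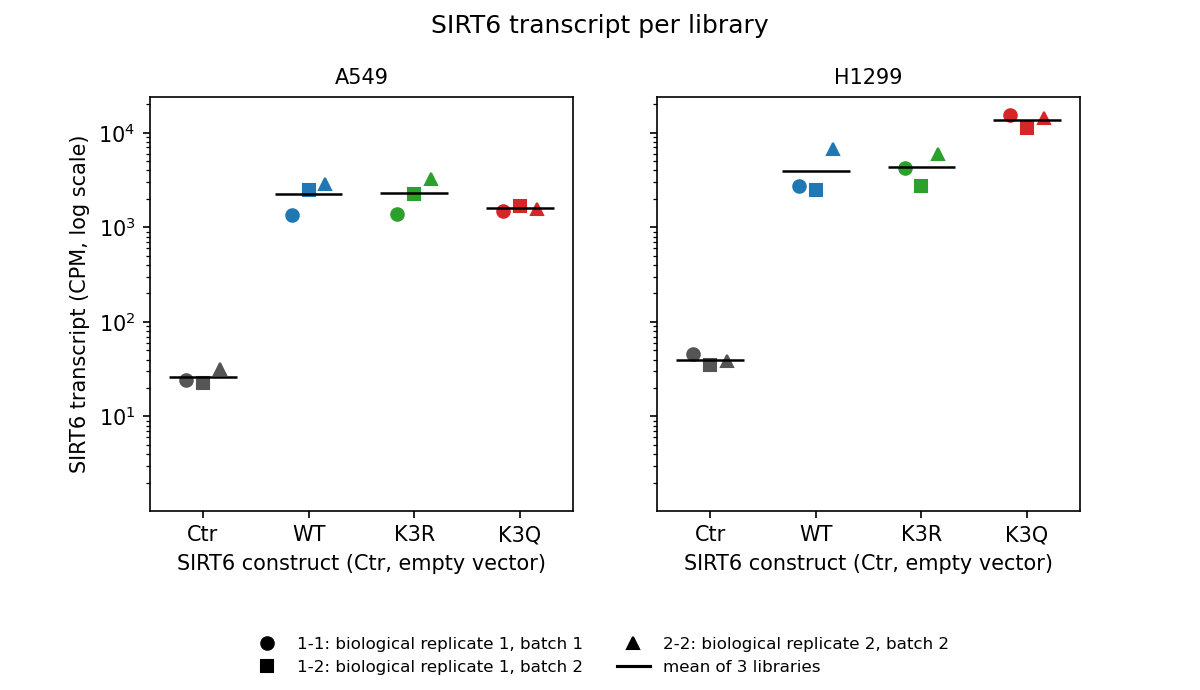
SIRT6 transcript in CPM, on a log axis, in each of the 24 libraries, by line and construct. Symbols are the replicate and batch and lines are group means: the means with a construct are 1584 to 2291 CPM in A549 and 3984 to 13620 CPM in H1299, against 26.0 and 39.4 CPM in Ctr.

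In A549, wild-type SIRT6 raised KIF1A, a kinesin that carries synaptic vesicle precursors, from 7.25 ± 2.87 to 42.4 ± 20.2 CPM (log2 2.52 ± 0.32, adjusted p = 0.0158; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, n = 3 and 3). L1CAM, a neural cell adhesion molecule, rose from 13.8 ± 4.70 to 48.9 ± 10.5 CPM (log2 1.82 ± 0.24, adjusted p = 0.0195). The short-chain dehydrogenase DHRS2 rose by 1.84 ± 0.21 (adjusted p = 0.00973), the galanin receptor GALR2 by 2.00, the lipoprotein receptor LSR by 1.26 and the lectin-like gene KLRG2 by 1.32 on the log2 scale. SPANXB1, a sperm protein gene of the X chromosome whose family holds near-identical copies, was higher by 2.58, a value left uncertain by reads shared among the copies. Genes that fell were JCAD, which codes for a junction protein (log2 -1.07, adjusted p = 0.0409), the phosphodiesterase PDE1C (-1.0), the glycogenin gene GYG2 (-0.85), the p38-activating kinase MAP2K6 (-0.77) and the secreted phosphatidylserine-binding protein gene MFGE8, from 151 ± 13.4 to 93.8 ± 6.79 CPM (-0.68, adjusted p = 0.0158). NPY4R2 was lower by log2 -1.17, with the same doubt about a near-identical copy. Among the fixed gene lists, 1 of 26 epithelial junction genes passed (LSR), or 4 adjusted over the list alone. No member passed over all genes in the lists that moved as a whole with a preset correlation, and each of these calls was lost with an estimated correlation. Ribosomal proteins had a median log2 of 0.09 over 77 genes (adjusted p = 1.04e-05, and 0.643 with an estimated correlation), with RPL26 at 0.19 and RPL35A at 0.21. The 20 glycolysis genes had a median of 0.13 (adjusted p = 0.00366, and 0.714 with an estimated correlation), with PFKP at 0.28 and ALDOA at 0.53. The 24 NF-kB targets had a median of 0.21 (adjusted p = 0.00326, and 0.809 with an estimated correlation), with NFKBIA at 0.40 and ICAM1 at 1.26, and 1 passed adjusted over the list alone. With the replicate number as a block NFKBIA passed over all genes (adjusted p = 0.0492). It did not with biological replicate 1 summed, a fit without a term for the replicate, where SIRT6 alone passed. The 28 p53 targets had a median of -0.19 (adjusted p = 0.00105, and 0.714 with an estimated correlation), with ZMAT3 at -0.52 and SPATA18 at -0.63. Neuroendocrine markers, which another cell type would bring, had a median of 0.32 over 7 genes (adjusted p = 0.0106, and 0.643 with an estimated correlation), with CHGA at 1.42 and SCG2 at 0.96, and mitochondrially encoded mRNAs 0.14 over 13 genes (adjusted p = 0.00237, and 0.714 with an estimated correlation). In all, 17 of 16120 genes passed (11 higher, 6 lower). The count was 105 with the replicate number as a block, 178 by DESeq2, 1 in batch 2 alone and 374 without biological replicate 2, a choice made after seeing the data. That fit, here and below, holds 2 libraries of 1 biological replicate per group, so its counts may rest on technical spread and do not rank the constructs. It fell to 8 without Ctr 1-1, 3 without Ctr 1-2, 3 without WT 1-1, 7 without WT 1-2 and 10 without WT 2-2.

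K3R in A549 raised the genes KIF1A (7.25 ± 2.87 to 41.8 ± 22.4 CPM, log2 2.49 ± 0.32, adjusted p = 0.0153; edgeR quasi-likelihood test, Benjamini-Hochberg, n = 3 and 3), DHRS2 (10.6 ± 1.38 to 40.1 ± 12.5 CPM, log2 1.91, adjusted p = 0.00465) and GALR2 (log2 2.19, adjusted p = 0.0037). SPANXB1 was higher by 2.63, with the doubt given above. Falls were seen in JCAD (log2 -1.28, adjusted p = 0.0153), PDE1C (-1.05), GYG2 (-0.91), MFGE8 (-0.82, from 151 ± 13.4 to 85.2 ± 3.37 CPM) and FBN2, the gene of the microfibril protein fibrillin 2 (-0.73, adjusted p = 0.0216). Of 26 epithelial junction genes, EPCAM (log2 1.46, adjusted p = 0.0485) and LSR (1.43, adjusted p = 0.0037) rose, and 5 passed adjusted over the list alone (list adjusted p = 0.000352, and 0.578 with an estimated correlation). Of 34 mesenchymal and matrix genes none passed over all genes, and 1 higher and 3 lower passed adjusted over the list alone, with ZEB2 at -1.94 and SPARC at -1.51 (list adjusted p = 0.0345, and 0.578 with an estimated correlation). The 30 NRF2 targets had a median log2 of 0.14 and none passed over all genes, with OSGIN1 at 0.61 and SRXN1 at 0.75, and 2 passed adjusted over the list alone (list adjusted p = 0.000352, and 0.578 with an estimated correlation). The Wnt targets NKD1 and NOTUM stood at 0.82 and 1.76 without passing over all genes, 2 of 14 targets passed adjusted over the list alone, and the list gave an adjusted p = 0.0165, or 0.362 with an estimated correlation. With the replicate number as a block, which pairs these libraries, ZEB2 (adjusted p = 0.0401), OSGIN1 (0.0363), NKD1 (0.0335) and NOTUM (0.0419) passed over all genes. With biological replicate 1 summed, a fit without a term for the replicate, SIRT6 alone passed. Neuroendocrine markers had a median of 0.49 (adjusted p = 0.00119, and 0.293 with an estimated correlation), with CHGA at 1.32 and SYP at 0.49, and mitochondrially encoded mRNAs 0.13 (adjusted p = 0.00119, and 0.578 with an estimated correlation). In all, 19 genes passed (11 higher, 8 lower). The count was 88 with the replicate number as a block, 162 by DESeq2, 1 in batch 2 alone and 394 without biological replicate 2. It fell to 9 without Ctr 1-1, 6 without Ctr 1-2, 5 without K3R 1-1 and 7 without K3R 1-2.

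K3Q in A549 changed SIRT6 and 3 other genes. LSR rose from 18.7 ± 3.27 to 41.8 ± 4.85 CPM (log2 1.16 ± 0.15, adjusted p = 0.0295; edgeR quasi-likelihood test, Benjamini-Hochberg, n = 3 and 3), FBN2 fell from 147 ± 2.89 to 75.9 ± 8.49 CPM (log2 -0.96 ± 0.10, adjusted p = 0.00785), and SFMBT2, a Polycomb-group gene, fell from 41.3 ± 14.3 to 19.9 ± 5.73 CPM (log2 -1.04, adjusted p = 0.0295). Of the genes raised by WT, chosen here after their values were seen, KIF1A stood at log2 0.84 (adjusted p = 0.502), DHRS2 at 0.29 (adjusted p = 0.703) and L1CAM at 1.05 (adjusted p = 0.204). Of 34 mesenchymal and matrix genes none passed over all genes, with COL5A1 at -1.34 and SPARC at -2.24, and 1 higher and 9 lower passed adjusted over the list alone (list adjusted p = 0.00017, and 0.421 with an estimated correlation). Epithelial junction genes had a median of 0.24 over 26 genes and 3 passed adjusted over the list alone (list adjusted p = 2.24e-07, and 0.421 with an estimated correlation). The medians were 0.29 for 30 NRF2 targets (adjusted p = 1.79e-09, and 0.421 with an estimated correlation), with SRXN1 at 0.71, and 0.09 for 77 ribosomal proteins (adjusted p = 6.54e-09, and 0.421 with an estimated correlation), with RPL31 at 0.41. G1/S genes had a median of 0.27 (CDT1 at 0.22), G2/M genes 0.31 (PRC1 at 0.73) and mitochondrially encoded mRNAs 0.20 (MT-ATP8 at 0.45), each with an adjusted p = 0.584 with an estimated correlation. The G1/S, G2/M and mitochondrially encoded lists moved with the library that stands apart: Ctr 2-2 scored 53.74 on the first principal component and K3Q 2-2 -13.01. In the 2-2 against the 1-2 libraries of Ctr, WT and K3R the medians were -0.73 for G1/S genes (35 of 37 lower), -0.80 for G2/M genes (33 of 37 lower) and -0.22 for mitochondrially encoded mRNAs (7 of 13 lower). These shifts were lost with an estimated correlation (camera adjusted p of 0.413 or more). NRF2 targets (median -0.20, 14 of 30 lower, 7 higher) did not shift there with the preset correlation (camera adjusted p = 0.0958). Ribosomal proteins, mesenchymal and matrix genes and epithelial junction genes did not either (0.673, 0.917 and 0.425). In all, 4 genes passed (2 higher, 2 lower). Libraries 1-2 and 2-2 of K3Q were nearly identical. With the pair summed 1 gene passed, SIRT6, as in batch 2 alone, so LSR, FBN2 and SFMBT2 lost their calls. Neither of these fits holds a term for the replicate. With the replicate number as a block, which does not pair K3Q 2-2, 144 genes passed. With the block and the pair summed, a choice made after seeing the data, 221 passed. LSR, FBN2 and SFMBT2 passed in both block fits. DESeq2 called 154 genes, and 292 passed without biological replicate 2. The count was 1 without Ctr 1-1, 2 without Ctr 1-2, 14 without Ctr 2-2 and 1 without any 1 of the 3 K3Q libraries.

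**Figure D3:**
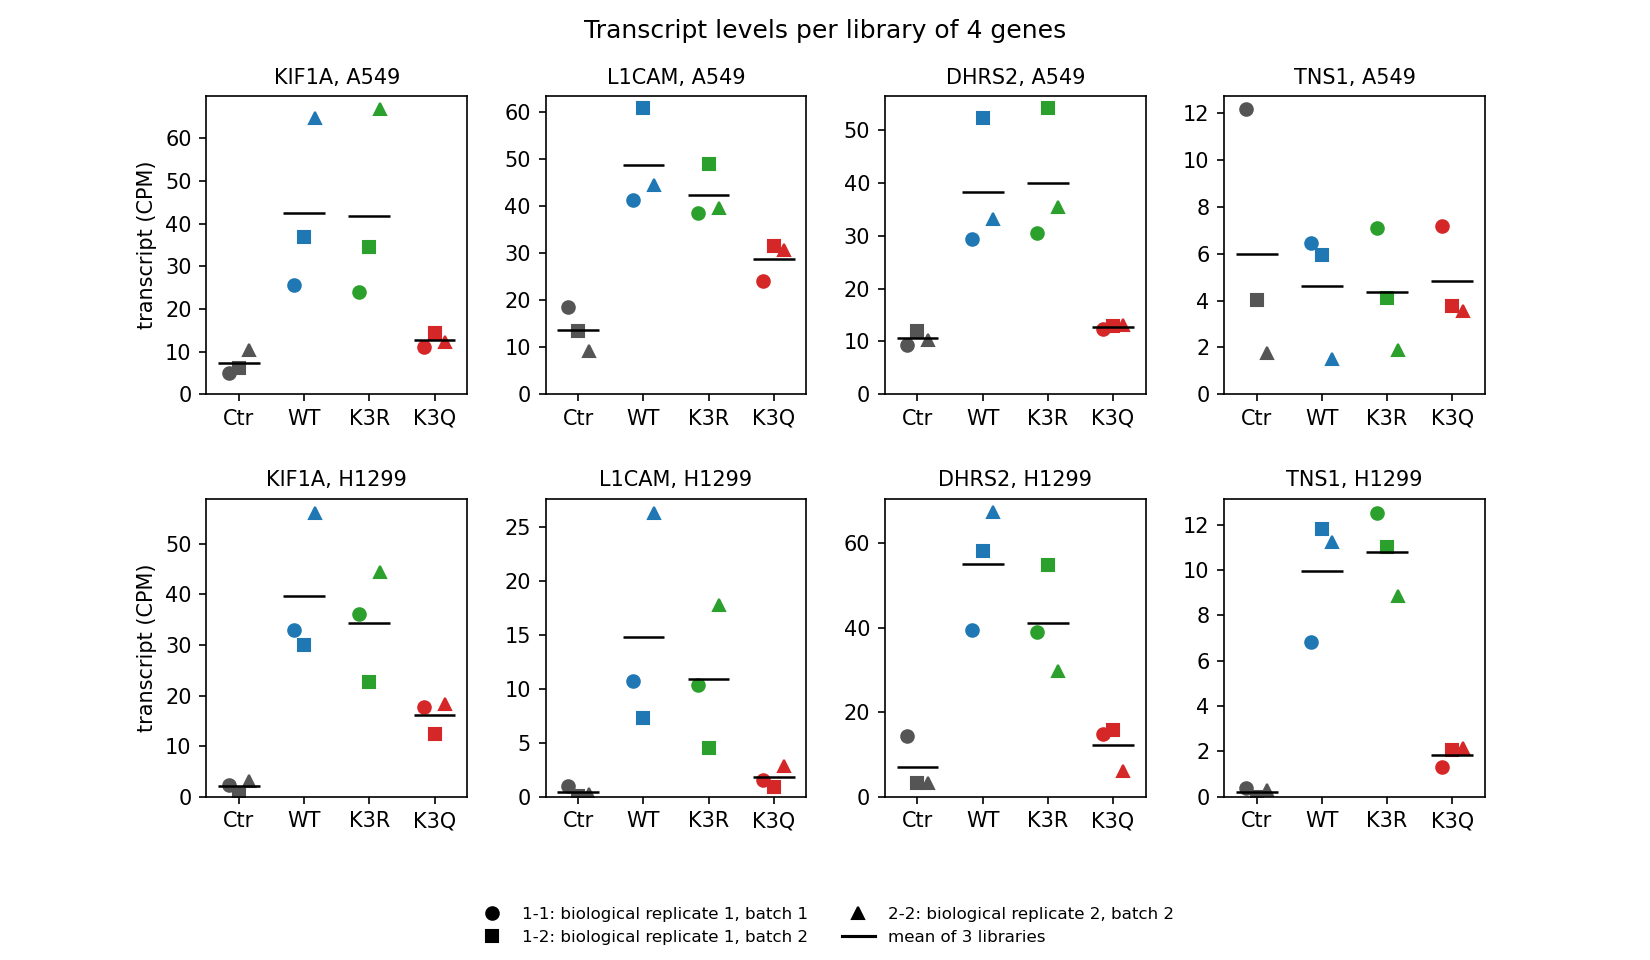
Transcript levels in CPM of KIF1A, L1CAM, DHRS2 and TNS1 in each library, A549 above and H1299 below, on linear axes from 0. Symbols are the replicate and batch and lines are group means: KIF1A averages 42.4 CPM in A549 WT and 39.8 CPM in H1299 WT, against 7.25 and 2.11 CPM in Ctr.

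The wild type and the acetylation-deficient mutant could not be told apart in A549. No gene passed for K3R against WT in the edgeR quasi-likelihood test (116 genes had an unadjusted p under 0.05, and 0 passed by DESeq2), and the genes with the lowest p were the heat shock gene HSPA6 (log2 2.13 ± 0.50), IRS4 (-5.51 ± 1.52) and GALNT16 (-0.66 ± 0.19), each with a Benjamini-Hochberg adjusted p of 1. Epithelial junction genes had a median log2 of 0.09 (list adjusted p = 0.000347, and 1 with an estimated correlation), with CLDN4 at 0.43 and DSG2 at 0.13. Without a low-count filter 5 genes passed.

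In the fit of construct and batch, K3Q differed from WT in A549 at SPANXB1 alone. The gene stood at 2.13 ± 1.09 against 9.98 ± 4.85 CPM (log2 -2.25 ± 0.24, adjusted p = 0.0248, edgeR quasi-likelihood test, Benjamini-Hochberg, n = 3 and 3). K3Q differed from K3R at the same gene, which stood at 10.8 ± 6.62 CPM in K3R (log2 -2.29 ± 0.24, adjusted p = 0.0204). The near-identical copies of this gene leave both values uncertain. Of the genes raised by WT, again chosen after their values were seen, DHRS2, at log2 -1.56 against WT (adjusted p = 0.0863) and -1.62 against K3R (adjusted p = 0.059), and KIF1A, at -1.68 and -1.65 (adjusted p = 0.185 and 0.315), did not pass. NF-kB targets had a median of -0.54 against WT (list adjusted p = 9.71e-07, and 0.611 with an estimated correlation), with TNFAIP3 at -1.04 and IL6 at -6.13, and -0.41 against K3R (list adjusted p = 0.000318, and 0.782 with an estimated correlation), with CXCL8 at -2.65 and CXCL1 at -0.97. None of these 24 genes passed over all genes or adjusted over the list alone. NF-kB targets also moved with the 2-2 libraries that K3Q 2-2 does not resemble: in the 2-2 against the 1-2 libraries of Ctr, WT and K3R their median was 0.86 (18 of 24 higher), with CXCL8 at 2.70, IL6 at 2.21, CXCL1 at 1.09 and TNFAIP3 at 0.76. That shift passed with the preset correlation (camera adjusted p = 6.46e-09) and was lost with an estimated one (0.258). Wnt targets had a median of -0.35 against WT (list adjusted p = 0.00794, and 0.241 with an estimated correlation) and -0.33 against K3R (0.00048, and 0.109 with an estimated correlation). NOTUM stood at -2.27 and -2.08 and NKD1 at -0.82 and -1.08, and in each comparison 4 of 14 passed, all lower, adjusted over the list alone. Against WT, mesenchymal and matrix genes stood at a median of -0.22 (COL12A1 at -0.82) with an adjusted p = 0.611 with an estimated correlation, and 2 passed adjusted over the list alone. K3Q libraries 1-2 and 2-2 were nearly identical, and with the pair summed both counts of 1 became 0. That fit holds no term for the replicate. With the replicate number as a block, which does not pair K3Q 2-2, 20 genes passed against WT and 7 against K3R. With the block and the pair summed, a choice made after seeing the data, 90 and 17 passed. SPANXB1 passed in each of these block fits. DESeq2 called 56 genes against WT and 23 against K3R. The count against WT was 0 without any 1 of the 6 libraries, and that against K3R was 0 without K3R 1-1, without K3R 2-2 and without any 1 of the K3Q libraries.

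In H1299, wild-type SIRT6 raised KIF1A from 2.11 ± 1.17 to 39.8 ± 14.3 CPM (log2 4.22 ± 0.39, adjusted p = 0.000335; edgeR quasi-likelihood test, Benjamini-Hochberg, n = 3 and 3; GRCh38 chromosome 2, 240713761 to 240821036). TNS1, the gene of the focal adhesion protein tensin 1 (chromosome 2, 217799588 to 218033982), rose from 0.230 ± 0.208 to 9.95 ± 2.73 CPM (log2 5.28 ± 0.47, adjusted p = 0.000239), and L1CAM (chromosome X, 153861514 to 153886174) from 0.426 ± 0.496 to 14.8 ± 10.1 CPM (log2 4.96 ± 0.77, adjusted p = 0.0044). Further rises were FBXO2, which codes for a ubiquitin ligase subunit that binds glycoproteins (log2 3.58), the Ras-like RASL10A (3.37), TMEM59L (3.35) and SERINC2 (3.20). The largest falls under the naming rule were ZNF704 (21.5 ± 4.76 to 3.28 ± 1.14 CPM, log2 -2.71 ± 0.32, adjusted p = 0.00169), RHOBTB1 (-2.46), the lysophosphatidic acid receptor LPAR1 (-2.31), C1orf21 (-2.29), the ESCRT-I gene MVB12B (-2.27), the transporter SLC16A9 (-2.05), the receptor phosphatase PTPRZ1 (-1.91) and the BMP receptor BMPR1B (-1.81). Of 32 mesenchymal and matrix genes 6 rose, among them COL5A1 (log2 2.92), MMP2 (2.36) and THBS1 (1.60), and 1 fell (list adjusted p = 0.0335, and 0.901 with an estimated correlation); 8 higher and 1 lower passed adjusted over the list alone. Of 18 TGF-beta targets 3 rose, TGFB2 (1.45) and ID1 (0.76) among them, and 2 fell, with 7 higher and 2 lower adjusted over the list alone (list adjusted p = 0.0335, and 0.901 with an estimated correlation). Among 20 NF-kB targets CXCL2 (-0.99), TRAF1 (-0.91) and IRAK2 (-0.73) fell, with 1 higher and 4 lower adjusted over the list alone (list adjusted p = 0.019, and 0.889 with an estimated correlation). Of 26 NRF2 targets 3 rose, the efflux pump gene ABCC3 (1.43) and the glutathione synthesis gene GCLM (0.42) among them, 3 also adjusted over the list alone (list adjusted p = 0.019, and 0.889 with an estimated correlation). Of 37 G2/M genes none passed, with KIF20A at 0.23 and NEK2 at 0.24 (list adjusted p = 0.0335, and 0.901 with an estimated correlation). Glycolysis genes (2 higher and 1 lower of 20) and DNA repair genes (1 higher of 38), both tied to SIRT6 in other systems, did not shift as lists (adjusted p = 0.264 and 0.746). Of the endothelial markers 1 of 4 rose and of the lymphocyte markers 1 of 3, and neither list shifted (adjusted p = 0.306 and 0.594). Some of these genes and lists also moved with biological replicate 2, a comparison chosen after seeing the data. In the 2-2 against the 1-2 libraries of the 4 constructs MMP2 was higher by log2 0.80. The medians there were 0.26 for mesenchymal and matrix genes (7 of 31 higher), 0.35 for TGF-beta targets (7 of 18 higher, 1 lower) and 0.22 for NRF2 targets (8 of 26 higher). Each group holds 1 library 2-2, so a shift shared by the constructs cancels and adds only to the spread. A shift that differs between constructs would not cancel. Without WT 2-2 some of the genes named here did not pass: THBS1 (log2 1.35, adjusted p = 0.13), ID1 (0.53, adjusted p = 0.182), TRAF1 (-0.96, adjusted p = 0.0541), IRAK2 (-0.75, adjusted p = 0.0615), ABCC3 (1.04, adjusted p = 0.189) and GCLM (0.36, adjusted p = 0.179). In all, 659 of 16262 genes passed (410 higher, 249 lower), 315 of them by over 2-fold. The count was 1585 with the replicate number as a block, 1057 by DESeq2, 90 in batch 2 alone and 1493 without biological replicate 2. It fell to 300 without Ctr 1-2, 286 without Ctr 2-2, 329 without WT 1-1 and 245 without WT 2-2.

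K3R in H1299 raised TNS1 to 10.8 ± 1.84 CPM (log2 5.43 ± 0.46, adjusted p = 0.00016; edgeR quasi-likelihood test, Benjamini-Hochberg, n = 3 and 3), L1CAM to 10.9 ± 6.63 CPM (log2 4.52, adjusted p = 0.00812), KIF1A to 34.4 ± 10.9 CPM (log2 4.01, adjusted p = 0.000442) and FBXO2 to 37.0 ± 17.5 CPM (log2 3.16, adjusted p = 0.00776). ZNF704 (log2 -2.77), C1orf21 (-2.60), MVB12B (-2.33), RHOBTB1 (-2.18) and LPAR1 (-2.18) fell. Among 20 glycolysis genes PFKP (0.58), the lactate exporter gene SLC16A3 (0.58) and HK1 (0.47) rose, with 5 higher and 1 lower adjusted over the list alone (list adjusted p = 0.021, and 0.926 with an estimated correlation). Mesenchymal and matrix genes held 4 higher and 2 lower of 32 and did not shift as a list (adjusted p = 0.201). Without K3R 2-2, SLC16A3 (log2 0.48, adjusted p = 0.138) and HK1 (0.41, adjusted p = 0.0956) did not pass. In all, 528 genes passed (319 higher, 209 lower), 265 of them by over 2-fold. The count was 1392 with the replicate number as a block, 921 by DESeq2, 20 in batch 2 alone and 1203 without biological replicate 2. It fell to 224 without Ctr 1-2, 214 without Ctr 2-2, 102 without K3R 1-1 and 178 without K3R 2-2.

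K3Q in H1299, with the highest SIRT6 transcript of all groups, raised KIF1A to 16.1 ± 3.20 CPM (log2 2.92 ± 0.39, adjusted p = 0.0108; edgeR quasi-likelihood test, Benjamini-Hochberg, n = 3 and 3) and the mitochondrial protein gene FAM210A from 51.5 ± 4.41 to 93.1 ± 11.6 CPM (log2 0.85, adjusted p = 0.0108). UBASH3B, which codes for a protein tyrosine phosphatase, fell from 37.9 ± 4.36 to 16.6 ± 1.38 CPM (log2 -1.19 ± 0.13, adjusted p = 0.00225). MVB12B (log2 -2.04), the leukaemia inhibitory factor receptor gene LIFR (-1.28), RAB15 (-0.89) and the formin gene FHOD3 (-0.83) also fell. Of the genes raised by WT, chosen here after their values were seen, L1CAM stood at 1.95 (adjusted p = 0.485) and DHRS2 at 0.86 (adjusted p = 0.583). The 77 ribosomal proteins had a median log2 of 0.25, none passing over all genes or adjusted over the list alone, with RPS9 at 0.44 and RPL28 at 0.40 (list adjusted p = 1.26e-18, and 0.837 with an estimated correlation). Oxidative phosphorylation subunits stood at 0.16 (UQCRC1 at 0.30), cholesterol synthesis genes at 0.22 (DHCR7 at 0.55), ATF4 targets at 0.23 (SHMT2 at 0.40), glycolysis genes at 0.19 (PFKP at 0.37) and heat shock genes at 0.18 (HSPA1A at 1.49), each with an adjusted p = 0.837 with an estimated correlation. With the replicate number as a block PFKP (adjusted p = 0.0458), RPS9, DHCR7 and HSPA1A (0.0352 each) passed over all genes. They did not with biological replicate 1 summed, a fit without a term for the replicate, where SIRT6 alone passed. In the 2-2 against the 1-2 libraries of the 4 constructs the medians were -0.22 for ribosomal proteins, -0.15 for oxidative phosphorylation subunits, 0.53 for ATF4 targets and -0.41 for heat shock genes. Such a shift cancels between K3Q and Ctr as far as both share it, since each holds 1 library 2-2. In all, 10 genes passed (4 higher, 6 lower). The count was 136 with the replicate number as a block, 126 by DESeq2, 1 in batch 2 alone and 2028 without biological replicate 2, a fit with 1 biological replicate per group that cannot rank the constructs. It fell to 3 without Ctr 1-1, 6 without Ctr 1-2, 4 without Ctr 2-2, 4 without K3Q 1-1 and 5 without K3Q 1-2.

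No gene passed for K3R against WT in H1299 in the edgeR quasi-likelihood test (486 had an unadjusted p under 0.05, and DESeq2 called 0). The retinaldehyde dehydrogenase gene ALDH1A2 (log2 -1.88 ± 0.46), ZNF711 (-1.0 ± 0.28) and DUSP23 (0.45 ± 0.13) had the lowest p, each with a Benjamini-Hochberg adjusted p of 0.999. Ribosomal proteins had a median of 0.10 (RPS9 at 0.28), oxidative phosphorylation subunits 0.11 (CYC1 at 0.31) and interferon-stimulated genes -0.18 (IRF9 at -1.08), each with an adjusted p = 0.95 with an estimated correlation. Without a low-count filter 9 genes passed, and 1 passed with all 24 libraries in the fit.

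K3Q differed from WT in H1299 at more genes than it differed from Ctr. The comparison does not tell which construct moved a gene from Ctr. COL5A1, MMP2 and THBS1, lower in K3Q here, rose with WT against Ctr. SIRT6 transcript was also 3.43-fold higher in K3Q than in WT. MGMT, the DNA repair methyltransferase gene (GRCh38 chromosome 10, 129467184 to 129768007), stood at 17.8 ± 3.63 CPM in K3Q against 5.83 ± 1.03 in WT (log2 1.60 ± 0.21, adjusted p = 0.00357; edgeR quasi-likelihood test, Benjamini-Hochberg, n = 3 and 3), and VSTM1 was higher by 1.83 (adjusted p = 0.00637). NDRG1, a gene induced by hypoxia, stood at 1.12 ± 0.377 against 11.9 ± 10.9 CPM (log2 -3.43, adjusted p = 0.0334), the carboxypeptidase gene CPA4 at 2.61 ± 0.937 against 26.5 ± 19.3 CPM (-3.32, adjusted p = 0.0116) and SFMBT2 at 0.757 ± 0.155 against 7.04 ± 2.88 CPM (-3.19, adjusted p = 0.00539). Of 32 mesenchymal and matrix genes 6 were lower, COL5A1 (-4.41), MMP2 (-1.90) and THBS1 (-1.66) among them, and 1 higher and 9 lower passed adjusted over the list alone (list adjusted p = 0.000301, and 0.809 with an estimated correlation). Of 18 TGF-beta targets TGFB2 (-2.10) and TGFBI (-1.28) were among 4 lower and 1 was higher, with 8 lower and 1 higher adjusted over the list alone (list adjusted p = 0.00262, and 0.809 with an estimated correlation). The interferon-stimulated genes IFI44 (-2.25), IFIT1 (-1.56) and SAMD9 (-0.98) were lower, 3 of 26, or 5 adjusted over the list alone (list adjusted p = 0.00155, and 0.688 with an estimated correlation). Of 31 ATF4 and amino acid response genes SLC7A5 (1.13), SHMT2 (0.78) and PSPH (0.64) were higher, and 7 passed adjusted over the list alone (list adjusted p = 1.1e-06, and 0.809 with an estimated correlation). Of 77 ribosomal proteins RPS9 (0.52) passed over all genes and 31, all higher, adjusted over the list alone (list adjusted p = 7.47e-17, and 0.809 with an estimated correlation). Among 30 immediate early genes DUSP5 (0.92) and MYC (0.83) were higher, with 5 adjusted over the list alone (list adjusted p = 0.0077, and 0.809 with an estimated correlation). Some of these genes and lists also moved with biological replicate 2. In the 2-2 against the 1-2 libraries of the 4 constructs NDRG1 was higher by log2 1.62, MMP2 by 0.80 and TGFBI by 0.40, while IFIT1 stood at 0.71 (adjusted p = 0.0616). The medians there were 0.26 for mesenchymal and matrix genes, 0.35 for TGF-beta targets, 0.21 for interferon-stimulated genes, 0.53 for ATF4 targets, 0.27 for immediate early genes and -0.22 for ribosomal proteins. Shifts of this kind cancel between K3Q and WT as far as both share them, since each holds 1 library 2-2. Without WT 2-2, which stood apart on the first principal component, NDRG1 (log2 -2.32, adjusted p = 0.104), MMP2 (-1.48, adjusted p = 0.119), THBS1 (-1.38, adjusted p = 0.118), IFI44 (-2.09, adjusted p = 0.0932), IFIT1 (-1.18, adjusted p = 0.0778), SLC7A5 (0.96, adjusted p = 0.141), SHMT2 (0.69, adjusted p = 0.105), PSPH (0.59, adjusted p = 0.119) and RPS9 (0.51, adjusted p = 0.111) did not pass. In all, 563 genes passed (229 higher, 334 lower). The count was 1946 with the replicate number as a block, 1123 by DESeq2, 8 in batch 2 alone and 4033 without biological replicate 2. It was 211 without WT 1-1, 260 without WT 1-2, 169 without WT 2-2, 41 without K3Q 1-1, 109 without K3Q 1-2 and 849 without K3Q 2-2.

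Against K3R in H1299, the acetylation mimetic K3Q stood higher at ZNF711 (3.38 ± 0.626 against 0.858 ± 0.0945 CPM, log2 1.99 ± 0.27, adjusted p = 0.0129, edgeR quasi-likelihood test, Benjamini-Hochberg, n = 3 and 3). Also higher were RFPL4A (1.69), MN1 (1.63), MGMT (1.52), the semaphorin gene SEMA4D (1.25), the sialyltransferase gene ST6GAL1 (1.10), the insulin receptor adaptor gene GRB14 (1.07) and FBN2 (0.96, 43.4 ± 3.59 against 22.6 ± 6.24 CPM). The comparison does not tell which construct moved a gene from Ctr. Against Ctr, K3R lowered FBN2 and raised TNS1. Lower were CPA4 (log2 -3.10), SERINC2 (-2.72), TNS1 (1.86 ± 0.469 against 10.8 ± 1.84 CPM, log2 -2.57 ± 0.36, adjusted p = 0.0129), the Rac activator gene DOCK2 (-2.18), the retinoic acid-binding protein gene CRABP2 (-1.98), the amino acid transporter gene SLC6A17 (3.84 ± 1.04 against 14.6 ± 3.31 CPM, log2 -1.96 ± 0.23, adjusted p = 0.00511) and the planar polarity gene PRICKLE1 (-1.96). RFPL4A belongs to a family of similar copies and is uncertain. COL5A1 (-3.44) was the 1 mesenchymal and matrix gene of 32 to pass, with 5 lower adjusted over the list alone (list adjusted p = 0.00139, and 0.857 with an estimated correlation), and TGFB2 (-1.55) the 1 TGF-beta target of 18, with 1 higher and 7 lower adjusted over the list alone (list adjusted p = 0.00201, and 0.857 with an estimated correlation). ATF4 targets had a median of 0.49 with none passing, PSPH at 0.56 and SHMT2 at 0.60 (list adjusted p = 4.52e-07, and 0.857 with an estimated correlation), and ribosomal proteins 0.20, RPL19 at 0.29 (list adjusted p = 3.88e-10, and 0.857 with an estimated correlation). With the replicate number as a block PSPH (adjusted p = 0.0196) and SHMT2 (0.0399) passed over all genes. Neither passed with biological replicate 1 summed, a fit without a term for the replicate, where no gene did. Mesenchymal and matrix genes, TGF-beta targets, ATF4 targets and ribosomal proteins moved with biological replicate 2, as given above. That movement cancels here as far as K3Q and K3R share it. K3R 2-2 stood apart on the first principal component, and without it RFPL4A, MN1, SEMA4D, ST6GAL1, GRB14, FBN2, CPA4, DOCK2, CRABP2, PRICKLE1 and TGFB2 did not pass (adjusted p of 0.0819 to 0.192). In all, 73 genes passed (15 higher, 58 lower), and SIRT6 itself was 3.15-fold higher in K3Q without passing. The count was 526 with the replicate number as a block, 337 by DESeq2, 0 in batch 2 alone (edgeR) and 1293 without biological replicate 2. It was 0 without K3Q 1-1, 4 without K3Q 1-2, 5 without K3Q 2-2, 4 without K3R 1-1 and 11 without K3R 2-2.

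**Figure D4:**
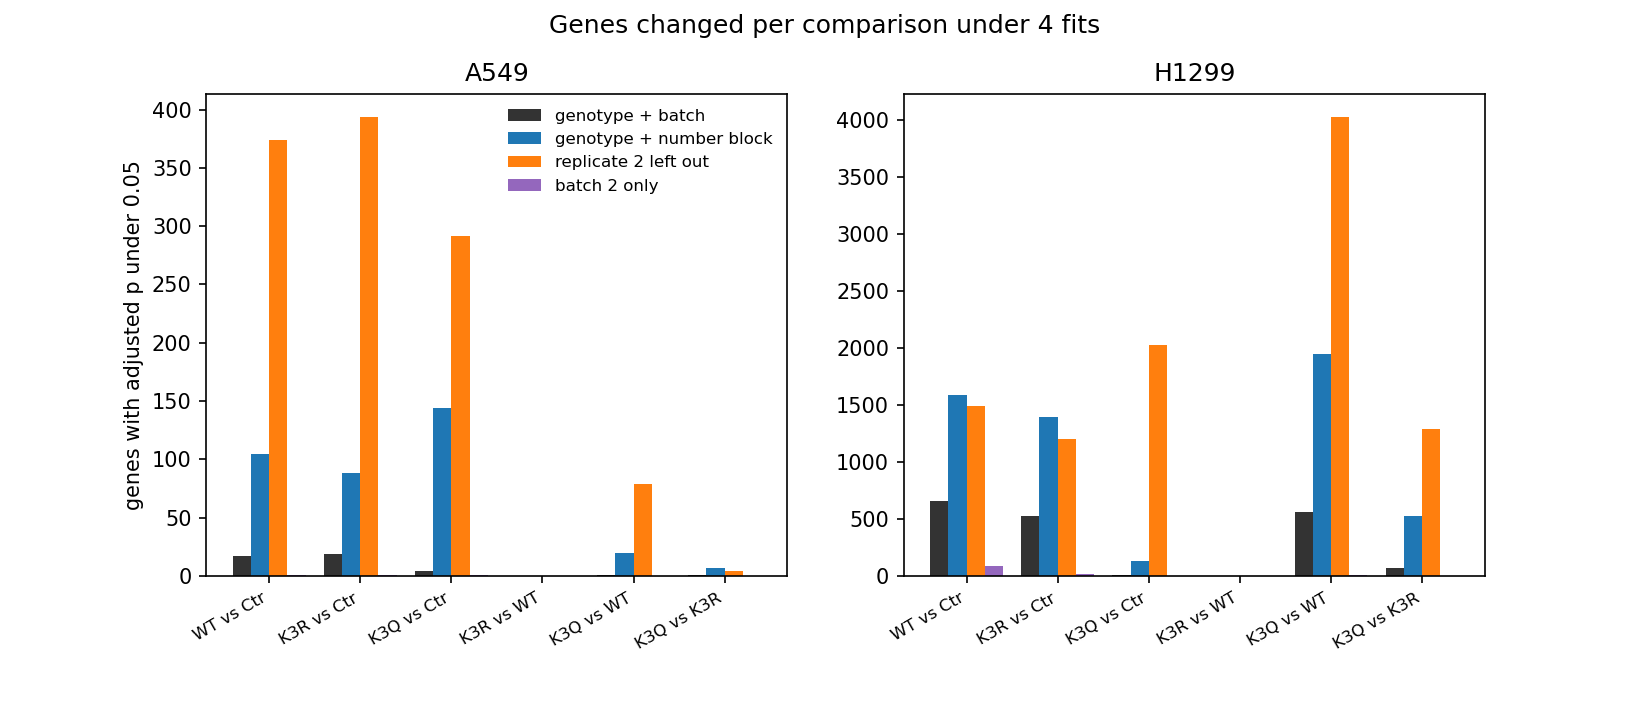
Number of genes with a Benjamini-Hochberg adjusted p under 0.05 in each comparison, A549 left and H1299 right on separate axes from 0. Bars are 4 fits: construct and batch, construct with the replicate number as a block, biological replicate 2 left out (1 biological replicate per group), and batch 2 only. The number does not pair A549 K3Q 2-2. For WT against Ctr in H1299 they stand at 659, 1585, 1493 and 90, and for K3Q against Ctr at 10, 136, 2028 and 1.

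The responses to the constructs were compared within each line, without SIRT6 itself. They share the same Ctr libraries, which alone gave a correlation of log2 fold changes across genes of about 0.50 in 20 simulations. The simulations drew each library independently, without the shifts by replicate number that constructs share. Their noise, and so their covariance, may therefore differ from that of the data. WT and K3R correlated at 0.797 in A549 and 0.861 in H1299 (Spearman 0.761 and 0.763). The covariance was 0.114 against a simulated 0.0538 in A549, and 0.239 against 0.0467 in H1299. K3Q correlated with WT at 0.543 in A549 and 0.466 in H1299 (SE over left-out libraries 0.227 and 0.143). With K3R it correlated at 0.569 and 0.567 (SE 0.232 and 0.119). Each of these correlations lies within its SE of the simulated 0.50. A response of WT or K3R alone also lowers a correlation, so closeness to 0.50 does not show that nothing is shared. The covariances were above the simulated ones by 0.034, 0.0433, 0.0377 and 0.0606 in the same order. The SDs over the simulations were 0.00163, 0.00136, 0.00142 and 0.00108, and they do not hold shifts by replicate number. Whether K3Q shares a response with WT or K3R stays open. In H1299, 250 genes rose with both WT and K3R, of 409 and 318, where independent lists would share 8, and 132 fell with both, of 249 and 209, where independent lists would share 3.20. No gene moved in opposite directions. In A549, 7 genes rose with both, of 10 and 10, and 5 fell with both, of 6 and 8. Part of these excesses may come from the shared Ctr libraries, which are too few to split. Genes are not independent replicates.

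Some genes rose in both lines. With WT these were KIF1A, L1CAM, DHRS2, LSR and SPANXB1, 5 genes of 10 called in A549 and 350 in H1299 among those tested in both, where independent lists would share 0.244. In H1299, DHRS2 rose by log2 3.10 (adjusted p = 0.00539; edgeR quasi-likelihood test, Benjamini-Hochberg), LSR by 0.87 (adjusted p = 0.00746) and SPANXB1 by 3.88 (adjusted p = 0.0434). With K3R, KIF1A, DHRS2, LSR and L1CAM rose in both lines and FBN2 fell in both (H1299 log2 -1.34, adjusted p = 0.00284). Over 14345 genes, the log2 fold changes of the lines correlated at 0.244 for WT, 0.266 for K3R, 0.188 for K3Q and 0.163 for K3Q against K3R. Over 100 splits of the libraries the permutation p were 0.09, 0.04, 0.3 and 0.19 (0.18, 0.16, 0.3 and 0.253 after Benjamini-Hochberg adjustment over the 4), so none passed. Spearman correlations were 0.203, 0.269, 0.191 and 0.102, with a permutation p of 0.45 after adjustment for each. The splits mix the replicate numbers, so shifts by number that both lines share can raise their correlations. These tests therefore cannot decide whether the lines respond alike.

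The lines differed at other genes, by an interaction test over all 24 libraries. FAM20C, a Golgi kinase gene, rose with WT in H1299 (log2 4.42) and stood at -0.03 in A549, a difference between the lines of -4.43 ± 0.52 (adjusted p = 0.000291; edgeR quasi-likelihood test, Benjamini-Hochberg). TFPI, the tissue factor pathway inhibitor gene, rose with WT by 1.36 in H1299 and stood at -0.40 in A549 (difference -1.76 ± 0.18, adjusted p = 8.06e-05). NID2, a basement membrane gene, rose with K3R in A549 (1.61, adjusted p = 0.0485) and fell in H1299 (-2.06, adjusted p = 0.00955), a difference of 3.66 ± 0.42 (adjusted p = 0.000237). TNS1 rose with K3R in H1299 alone of the 2 lines (difference -5.75 ± 0.77, adjusted p = 0.00118). SIRPA fell with K3Q in H1299 (-2.69) and stood at -0.44 in A549 (difference 2.24 ± 0.26, adjusted p = 0.000694). MGMT was higher in K3Q than in K3R in H1299 (1.52) and stood at -0.10 in A549 (difference -1.62 ± 0.26, adjusted p = 0.0133). In all, the change differed between the lines at 133 genes for WT, 86 for K3R, 3 for K3Q and 20 for K3Q against K3R, of 18102 tested. With the replicate number as a block these counts were 434, 301, 37 and 94. That fit holds A549 K3Q 2-2, which the number does not pair, so these counts, the last 2 most directly, carry that doubt. In batch 2 alone they were 24, 6, 0 and 0 (edgeR). The near-identical A549 K3Q pair enters the last 2 counts, which were 1 and 6 with that pair summed. The WT against Ctr count was 86 without A549 Ctr 1-1, 61 without A549 WT 1-1, 83 without A549 WT 1-2, 69 without H1299 Ctr 1-2, 69 without H1299 Ctr 2-2, 71 without H1299 WT 2-2. The K3R against Ctr count was 41 without A549 Ctr 1-1, 54 without A549 Ctr 1-2, 36 without A549 K3R 1-1, 46 without A549 K3R 1-2, 40 without H1299 Ctr 1-2, 38 without H1299 Ctr 2-2, 30 without H1299 K3R 1-1, 39 without H1299 K3R 2-2. The K3Q against Ctr count was 1 without A549 Ctr 1-1, 5 without A549 Ctr 2-2, 1 without A549 K3Q 1-2, 1 without A549 K3Q 2-2, 1 without H1299 Ctr 1-1, 1 without H1299 Ctr 1-2, 6 without H1299 Ctr 2-2, 1 without H1299 K3Q 1-2. The K3Q against K3R count was 3 without A549 K3R 1-1, 13 without A549 K3R 1-2, 9 without A549 K3R 2-2, 2 without A549 K3Q 1-1, 5 without A549 K3Q 1-2, 6 without A549 K3Q 2-2, 7 without H1299 K3R 1-1, 9 without H1299 K3R 2-2, 7 without H1299 K3Q 1-1, 11 without H1299 K3Q 1-2, 3 without H1299 K3Q 2-2.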

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

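The tests of the labelled batch, of the mitochondrial share, of the SIRT6 transcript level in K3Q and of a common culture for the A549 K3Q pair were chosen after their results were seen, as was the count of splits that mix both lines. The test that thins the A549 libraries was chosen after the principal components were seen and its bound written before its own value. The test of the K3Q responses was written after the counts without biological replicate 2 were seen and before its own value.

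The effect of a construct differed between A549 and H1299, by a test of the difference itself, at 133 genes for WT, 86 for K3R, 3 for K3Q and 20 for K3Q against K3R. Leaving out single libraries gave 61 to 134, 30 to 90, 1 to 6 and 2 to 15. The A549 minus H1299 differences in log2 fold change for WT were 1.99 for MVB12B, 1.49 for SHROOM3, 1.94 for BMP6, -1.76 for TFPI, -1.23 for FAM3C and -4.43 for FAM20C. For K3R they were 3.66 for NID2, 1.94 for SHROOM3, 2.05 for MVB12B, -1.66 for TFPI, -1.25 for FAM210A and -5.75 for TNS1. For K3Q they were 2.24 for SIRPA, 0.86 for AMOTL1 and 2.46 for NID2, and for K3Q against K3R 1.80 for TFPI, 2.05 for SEMA3E, 0.93 for FAM3C, -1.62 for MGMT, -2.03 for MN1 and -1.13 for ADARB1. Over 30 splits drawn of 200, 2 were as large, the real one included, for WT (133 genes, highest other 251) and for K3R (86, highest other 195). The other one in each case kept the constructs of H1299 apart, so it holds the whole H1299 response and is no test of chance. For K3Q (3, highest other 1) and K3Q against K3R (20, highest other 11) 1 split, the real one, was as large. These highest others too kept the H1299 constructs apart. Among the 24 drawn splits that mixed the constructs in both lines, 0 were as large in any of the 4 comparisons, with highest edgeR counts of 8, 3, 0 and 0. Such splits remove the response of each line and do not test the difference between the lines by itself. The K3Q counts also rest on the near-identical A549 K3Q pair: with that pair summed they were 1 and 6, in a fit for which no splits were run, and in batch 2 alone 0 and 0 (edgeR, with 1135 and 1229 unadjusted and 50 and 100 by DESeq2 over all libraries), so chance is not taken as excluded for them.

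For comparisons of 3 libraries against 3 the 10 splits are too few. The real counts and the highest of the other splits were, in A549, 17 and 2 for WT against Ctr, 19 and 0 for K3R against Ctr, 4 and 0 for K3Q against Ctr, 0 and 1 for K3R against WT, 1 and 1 for K3Q against WT, and 1 and 0 for K3Q against K3R (edgeR; unadjusted and DESeq2 counts for the real 0 stand at 116 and 0). In H1299 they were 659 and 0, 528 and 0, 10 and 0, 0 and 0, 563 and 0, and 73 and 0 in the same order, with 486 unadjusted and 0 by DESeq2 for K3R against WT. The number of splits as large as the real one was 10 for K3R against WT in both lines, 2 for A549 K3Q against WT and 1 in the others.

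In H1299, K3Q against Ctr called 10 genes, against 659 for WT and 528 for K3R. A lower SIRT6 transcript level is excluded, since the lowest K3Q library held 1.65 times the SIRT6 CPM of the highest WT or K3R library. The counts do not give the protein, so a lower SIRT6 protein level stays open. Counts taken up by SIRT6 reads are excluded as the cause, since 7 genes passed with SIRT6 removed before scaling. The K3Q minus Ctr differences of libraries 1-2 and 2-2 correlated across genes at 0.295 (resampling SD 0.014), against 0.618 for WT and 0.655 for K3R, but a smaller K3Q response over similar noise would also lower it, and the count was 8 without K3Q 2-2 and 5 without K3Q 1-2, so whether the cultures responded alike stays open. Without biological replicate 2 the K3Q count was 2028 and the WT count 1493, but each group then holds 2 libraries of 1 biological replicate, so their spread may be technical and these counts cannot rank the constructs.

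A549 K3Q libraries 1-2 and 2-2 had a chi-square per degree of freedom of 2.60, under the 16.1 or more of every other pair of one group. K3Q 2-2 lay nearer to the 1-2 libraries of the other constructs (0.454 in log2 CPM) than to their 2-2 libraries (0.696), so the pair may come from one culture or one RNA. A wrong construct label on K3Q 2-2 stays open: its nearest library of another construct, K3R 1-2, stood at 4.49, which is under 2 times the value of the pair. No biological explanation was tested.

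The 2-2 libraries of A549 Ctr, WT and K3R stood apart from the 1-1 and 1-2 libraries on the first principal component. Of their totals 2 lay outside the range of the others, but library size is excluded as the cause, since with every A549 library thinned to the lowest total the gap to the other libraries was 48.8 or more in 20 thinnings, against 49.5 without thinning. The labelled batch is excluded as the source of this split, since 3 of 3 libraries 1-2, of the same batch as 2-2, lay nearer to 1-1. The labels do not say what a batch is, and differences within batch 2 stay open. The mitochondrial share was lower in these 3, at 6.19% in the highest against 6.57% in the lowest of the others, so a higher share did not set them apart, while a lower one goes with the pattern and stays open. A difference between the cultures of biological replicates 1 and 2 stays open and may have other technical sources.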

How the results depend on the processing

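Leaving out biological replicate 2, summing the near-identical A549 K3Q pair and leaving out libraries for the correlations were chosen after seeing the data. Over all settings, left-out libraries included, named genes other than SIRT6 that passed kept their direction and call in 1197 fits and lost the call in 583, and those that did not pass stayed so in 2317, passed in 149 and turned direction in 1 (A549 K3Q vs K3R: NDC80, at log2 -0.0437 without biological replicate 2). The SIRT6 difference for K3R/WT, which did not pass, also turned direction: SIRT6 level: A549 K3R vs WT was -0.13 without WT 1-1, -0.22 without K3R 2-2 and -0.0835 without biological replicate 2, and SIRT6 level: H1299 K3R vs WT was -0.14 without WT 1-1, -0.13 without WT 1-2, -0.23 without K3R 2-2 and -0.072 in batch 2 alone. Interaction genes kept the call in 333 fits and lost it in 96, and gene lists in 381 and 138. RLE scaling left each count of genes within 1.5 times. Counts are by edgeR unless DESeq2 is named, and A/B stands for A against B. The unadjusted counts for K3R/WT, where 0 genes passed, were 116 in A549 and 486 in H1299. Groups of 2 libraries called fewer genes in batch 2 alone and with replicate 1 summed. They called more without biological replicate 2, where each group holds 1 biological replicate, so group size alone does not set these counts. The fits of batch 2 alone and of summed replicate 1 hold no term for the replicate. The difference between biological replicates therefore enters their spread, and their low counts do not show that a change failed to repeat. How far this lowers the counts was not tested, and neither was the cause for the other settings. The effect of depth on these counts was not tested.

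Without a batch term, the number of genes was 3 for A549 WT/Ctr, 5 for A549 K3R/Ctr, 2 for A549 K3Q/Ctr, 0 for A549 K3Q/WT, 0 for A549 K3Q/K3R, 409 for H1299 WT/Ctr, 330 for H1299 K3R/Ctr, 188 for H1299 K3Q/WT, 33 for H1299 K3Q/K3R, 35 for WT/Ctr between lines, 22 for K3R/Ctr between lines, 1 for K3Q/Ctr between lines and 4 for K3Q/K3R between lines. The number of lists was 3 for H1299 WT/Ctr there. With the replicate number as a block, the number of genes was 105 for A549 WT/Ctr, 88 for A549 K3R/Ctr, 144 for A549 K3Q/Ctr, 20 for A549 K3Q/WT, 7 for A549 K3Q/K3R, 1585 for H1299 WT/Ctr, 1392 for H1299 K3R/Ctr, 136 for H1299 K3Q/Ctr, 1946 for H1299 K3Q/WT, 526 for H1299 K3Q/K3R, 434 for WT/Ctr between lines, 301 for K3R/Ctr between lines, 37 for K3Q/Ctr between lines and 94 for K3Q/K3R between lines. The number of lists was 2 for A549 K3R/WT and 9 for H1299 WT/Ctr there. SIRT6 stood at a log2 difference of 1.73 for H1299 K3Q/K3R (adjusted p = 0.000873) there. Without a low-count filter, the number of genes was 296 for A549 WT/Ctr, 315 for A549 K3R/Ctr, 641 for A549 K3Q/Ctr, 5 for A549 K3R/WT, 332 for A549 K3Q/WT, 228 for A549 K3Q/K3R, 1301 for H1299 WT/Ctr, 1276 for H1299 K3R/Ctr, 260 for H1299 K3Q/Ctr, 9 for H1299 K3R/WT, 1258 for H1299 K3Q/WT, 650 for H1299 K3Q/K3R, 506 for WT/Ctr between lines, 434 for K3R/Ctr between lines, 203 for K3Q/Ctr between lines and 305 for K3Q/K3R between lines. The correlation was 0.0443 for WT/Ctr between lines, 0.0585 for K3R/Ctr between lines, 0.0164 for K3Q/Ctr between lines, 0.0545 for K3Q/K3R between lines, 0.532 for A549 WT and K3R and 0.584 for H1299 WT and K3R there. SIRT6 stood at a log2 difference of -0.43 for A549 K3Q/WT (adjusted p = 0.0203), -0.46 for A549 K3Q/K3R (adjusted p = 0.0125) and 1.64 for H1299 K3Q/K3R (adjusted p = 1.87e-48) there. By DESeq2, the number of genes was 178 for A549 WT/Ctr, 162 for A549 K3R/Ctr, 154 for A549 K3Q/Ctr, 56 for A549 K3Q/WT, 23 for A549 K3Q/K3R, 1057 for H1299 WT/Ctr, 921 for H1299 K3R/Ctr, 126 for H1299 K3Q/Ctr, 1123 for H1299 K3Q/WT, 337 for H1299 K3Q/K3R, 310 for WT/Ctr between lines, 240 for K3R/Ctr between lines, 50 for K3Q/Ctr between lines and 100 for K3Q/K3R between lines. SIRT6 stood at a log2 difference of 1.65 for H1299 K3Q/K3R (adjusted p = 0.0178) there. With all 24 libraries in one fit, the number of genes was 25 for A549 K3Q/Ctr, 3 for A549 K3Q/WT, 43 for H1299 K3Q/Ctr, 1 for H1299 K3R/WT and 160 for H1299 K3Q/K3R. The SIRT6 log2 difference was 1.66 for H1299 K3Q/K3R (adjusted p = 0.0148) there. With biological replicate 1 summed, the number of genes was 1 for A549 WT/Ctr, 1 for A549 K3R/Ctr, 1 for A549 K3Q/Ctr, 0 for A549 K3Q/WT, 0 for A549 K3Q/K3R, 93 for H1299 WT/Ctr, 44 for H1299 K3R/Ctr, 1 for H1299 K3Q/Ctr, 25 for H1299 K3Q/WT, 0 for H1299 K3Q/K3R, 9 for WT/Ctr between lines, 1 for K3R/Ctr between lines, 0 for K3Q/Ctr between lines and 0 for K3Q/K3R between lines. The number of lists was 4 for H1299 K3R/Ctr there. SIRT6 stood at a log2 difference of 1.58 for H1299 K3Q/WT (adjusted p = 0.168) there. In batch 2 alone, the number of genes was 1 for A549 WT/Ctr, 1 for A549 K3R/Ctr, 1 for A549 K3Q/Ctr, 0 for A549 K3Q/WT, 0 for A549 K3Q/K3R, 90 for H1299 WT/Ctr, 20 for H1299 K3R/Ctr, 1 for H1299 K3Q/Ctr, 8 for H1299 K3Q/WT, 0 for H1299 K3Q/K3R, 24 for WT/Ctr between lines, 6 for K3R/Ctr between lines, 0 for K3Q/Ctr between lines and 0 for K3Q/K3R between lines. The number of lists was 0 for A549 K3R/WT, 16 for A549 K3Q/WT and 4 for H1299 K3R/Ctr there. SIRT6 stood at a log2 difference of -0.072 for H1299 K3R/WT (adjusted p = 1) and 1.47 for H1299 K3Q/WT (adjusted p = 0.312) there. Without biological replicate 2, the number of genes was 374 for A549 WT/Ctr, 394 for A549 K3R/Ctr, 292 for A549 K3Q/Ctr, 79 for A549 K3Q/WT, 4 for A549 K3Q/K3R, 1493 for H1299 WT/Ctr, 1203 for H1299 K3R/Ctr, 2028 for H1299 K3Q/Ctr, 4033 for H1299 K3Q/WT, 1293 for H1299 K3Q/K3R, 581 for WT/Ctr between lines, 521 for K3R/Ctr between lines, 444 for K3Q/Ctr between lines and 132 for K3Q/K3R between lines. The SIRT6 log2 difference was -0.0835 for A549 K3R/WT (adjusted p = 0.999) and 1.94 for H1299 K3Q/K3R (adjusted p = 2.71e-09) there. With the near-identical A549 K3Q pair summed, the number of genes was 1 for A549 K3Q/Ctr, 0 for A549 K3Q/WT, 0 for A549 K3Q/K3R, 1 for K3Q/Ctr between lines and 6 for K3Q/K3R between lines. The number of lists was 6 for A549 K3Q/K3R there. With that pair summed and the block, the number of genes was 221 for A549 K3Q/Ctr, 90 for A549 K3Q/WT and 17 for A549 K3Q/K3R. With an estimated correlation, 0 lists passed in each of the 12 comparisons.

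Leaving out single libraries gave 3 to 18 for A549 WT/Ctr, 5 to 19 for A549 K3R/Ctr, 1 to 14 for A549 K3Q/Ctr, -0.21 to 0.20 for SIRT6 in A549 K3R/WT, 0 to 0 for A549 K3Q/WT, 0 to 1 for A549 K3Q/K3R, 245 to 495 for H1299 WT/Ctr, 102 to 553 for H1299 K3R/Ctr, 3 to 8 for H1299 K3Q/Ctr, -0.23 to 0.77 for SIRT6 in H1299 K3R/WT, 41 to 849 for H1299 K3Q/WT, 1.51 to 2.41 for SIRT6 in H1299 K3Q/WT, 0 to 82 for H1299 K3Q/K3R, 61 to 134 for WT/Ctr between lines, 30 to 90 for K3R/Ctr between lines, 1 to 6 for K3Q/Ctr between lines, 2 to 15 for K3Q/K3R between lines, 0.161 to 0.28 for the correlation of K3R/Ctr between lines, 0.0771 to 0.205 for the correlation of K3Q/Ctr between lines, 0.688 to 0.855 for the correlation of A549 WT and K3R, 0.769 to 0.912 for the correlation of H1299 WT and K3R, 0.375 to 0.676 for the correlation of H1299 WT and K3Q and 0.461 to 0.736 for the correlation of H1299 K3R and K3Q.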

Other observations

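The comparison of biological replicates was chosen after the principal components were seen, and the genes named from it after their values were seen.

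Within batch 2, biological replicate 2 differed from replicate 1 in both lines, over the constructs together (K3Q left out in A549). Targets of the stress-induced transcription factor ATF4 were higher: 28 of 31 in A549 and 19 of 30 in H1299. TRIB3 was higher by log2 2.82 in A549 and 2.28 in H1299, CHAC1 by 3.28 and 1.94, DDIT3 by 2.66 and 2.28, and SESN2, which is also among the p53 targets, by 2.43 and 1.90. The stress cytokine gene GDF15, a p53 target, was higher by 1.55 and 4.43, while the p53 targets did not shift as a list (adjusted p = 0.233 and 0.645). Genes of G1/S and DNA replication were lower, 35 of 37 in A549 and 25 of 37 in H1299, with CDC6 at -1.01 and -0.61 and RRM2 at -1.07 and -0.45. Heat shock genes were lower (17 and 11 of 19; HSPA8 at -1.48 in A549), and G2/M genes were lower in 33 of 37 and 6 of 37. In A549, NF-kB targets were higher in 18 of 24 and lower in 1 (CXCL8 at 2.70), and in H1299 autophagy and lysosome genes were higher in 22 of 36 (SQSTM1 at 1.43). Mitochondrially encoded mRNAs were lower in 7 of 13 in A549 and higher in 9 of 13 in H1299. None of these lists passed with an estimated correlation (adjusted p of 0.237 or more). In all, 5500 of 15275 genes differed in A549 (2796 higher, 2704 lower) and 1895 of 15227 in H1299 (1150 higher, 745 lower). In A549 the 10 splits are too few (5500, highest other 0; 1 split as large). In H1299 1 of 32 splits was as large, the real one (1895, highest other 9), but 8 of these part the libraries of each construct as the real one does, which are too few. The construct is balanced over these replicates, and the culture, its handling and its RNA cannot be told apart.

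Whether H1299 libraries with more SIRT6 transcript responded more was tested as a hypothesis over the 6 WT and K3R libraries, on 382 genes changed the same way by both. These genes were called against Ctr in the same libraries, so they were not chosen independently of the responses. The mean response correlated with log2 SIRT6 CPM at a Pearson r of 0.768 (exact permutation p = 0.103) and a Spearman rho of 0.486 (exact permutation p = 0.356), over 720 permutations, two-sided, or 0.206 and 0.356 after Benjamini-Hochberg adjustment over both. The permutations exchange the libraries freely, although the number pairs WT with K3R. Without WT 2-2 and K3R 2-2, the libraries farthest from the median SIRT6 level, r was -0.352, so the relation rests on those libraries. They are the ones of biological replicate 2, so SIRT6 level and replicate cannot be told apart. Within batch 2, r was 0.942 over 4 libraries, which include both of those and are too few for a test, and batch 1 holds 2.

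Whether genes changed by WT in H1299 moved the same way in A549 was tested on the 588 of them measured there. Of these, 403 (68.5%) moved the same way by the fitted changes and 69.0% by differences of mean log2 CPM, the measure used for the splits, where the highest of the 9 other splits of the A549 libraries gave 66.7%. The 10 splits are too few.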
